A study of Mus musculus with 6 samples.

How the data were processed

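RNA was measured by SMART-seq2 sequencing in 6 libraries of muscle stem cells from 3-month-old C57BL/6 mice, with 2 libraries each of CPEB4 RIP, IgG RIP and input. Sequencing was paired-end on a BGI DNBSEQ-G400, per the labels. Reads were aligned with HISAT2 to the mm10 build and counted per gene with featureCounts, per the labels. Their versions, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. The deposited count table holds raw counts per gene, 1 column per library, with no normalization by the authors. A second deposited table holds FPKM, fragments per kilobase of gene model scaled by a library total. In the FPKM table each library has 1 scaling constant, which differs in proportion from the sum of the counts (by a ratio of 0.986 to 1.21), so the total the authors used is not the sum of assigned counts. What that total counts and the tool that made the FPKM values are not given in the sources used here.

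Total counts were 9018323 to 20843042 per library over 55376 genes. Gene identity was taken from the symbols in the count table. A RefSeq gene table on GRCm38, the mm10 assembly, matched 38890 of the symbols (70.2%) and 16617 of the genes tested, and gave the positions printed. The PCR reads carry no molecular identifiers here, so counts are not independent molecules and the depth limits only counting error. The number of genes expected at equal depth was computed by rarefaction to the lowest total.

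Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 18054, and libraries were scaled by TMM, trimmed means of log ratios. A quasi-likelihood model (glmQLFit, glmQLFTest) with group as its only term was fitted to all 6 libraries, with 3 residual degrees of freedom. The 3 comparisons were CPEB4 RIP with IgG RIP, CPEB4 RIP with input, and IgG RIP with input. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was 0.05. CPM values are normalised with the TMM factors, and SD is over the 2 libraries of a group. SE of a log2 fold change was derived as its absolute value divided by the square root of the test's F statistic. The CPEB4 RIP libraries enter both of the first comparisons, so the relation of their fold changes was set beside 20 simulations of unchanged groups that share those libraries.

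The comparisons, 27 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Lists with at least 5 genes tested entered limma's camera (limma 3.58.1) with a preset correlation of 0.01 on log CPM with a prior count of 2, adjusted over the lists, and camera with an estimated correlation and fry as alternatives. Counts of members past the edgeR test were adjusted over all genes and, separately, over the list alone. The named genes were the 10 widest rises and 5 widest falls of the comparisons with CPEB4 RIP, and 5 each way for IgG RIP with input. They had to pass the test, have a mean of at least 10 CPM and have groups of libraries that do not overlap, and symbols without a gene name were passed over. Where fewer passed, the smallest p filled the number. For each list with a call or with at least 3 members past the test over IgG, up to 3 members with the smallest p were named. The 5 genes with the widest smaller fold over both backgrounds, and Cpeb4, Pax7, Myf5 and Myod1, completed the rule. Not every gene that the rule takes is printed. Other genes named in the text were chosen after their values were seen.

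The alternatives were DESeq2 size factors, library size alone, removal of genes of the mitochondrial genome, no low-count filter, a mean count of at least 20, the DESeq2 Wald test (DESeq2 1.42.0), only the 4 libraries compared, a term for replicate number, a 2-fold minimum, limma on the FPKM values with pseudocounts of 1 and 0.1 and with no filter, and each library left out in turn. A gene length offset (loess, span 0.3, on each library's deviation) and thinning to the lowest total were added after seeing the data. Gene length was taken from the ratio of counts to FPKM, so it is relative and available for all 18054 genes. Bootstrap intervals at 95% used 10000 resamples of list members.

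The steps were tested on simulated data with 200 genes changed 2-fold or 4-fold among 18054. A further list of genes was shifted by less than 2-fold, and calls of its members did not count as false. The edgeR test recovered 9% of genes changed 2-fold and 51% of those changed 4-fold, and 6.15% of its 65 calls were false. DESeq2 recovered 28% and 64%, and 28.6% of its calls were false. A shifted list had a camera p of 2.03e-12 and 2% of unchanged lists had a p under 0.05. The simulated genes were drawn independently, so these 2 values do not cover lists whose members move together. In the measured libraries the estimated correlation was 0.30 for ribosomal proteins and 0.57 for the mitochondrial genome. The length offset reduced a simulated shift of the shortest 10% of genes from 0.92 to 0.04 on the log2 scale. A planned test for the cytoplasmic polyadenylation element in 3' untranslated regions was not run, as genome sequence was not used here.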

Results

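RNA was recovered from muscle stem cells of 3-month-old C57BL/6 mice, isolated by fluorescence-activated cell sorting, and sequenced from SMART-seq2 libraries. SMART-seq2 is a full-length cDNA method for small amounts of RNA. RNA immunoprecipitation (RIP) uses an antibody to pull down a protein together with the RNA bound to it. Here the antibody was directed against CPEB4, a member of the CPEB family of RNA-binding proteins, which bind the cytoplasmic polyadenylation element of messages and regulate their translation. The 6 libraries formed 3 groups of 2, namely CPEB4 RIP, RIP with IgG, and input RNA. Assigned counts per library were 12679621 and 20843042 in CPEB4 RIP, 9018323 and 14225502 in IgG RIP, and 16314360 and 12426827 in input. The series' design text calls the CPEB4 libraries biological replicates and does not name animals or preparations, so p-values measure the spread between these samples, which may be technical in part. The 3 groups shared a single estimate of that spread per gene, although their replicates differed unequally. Chi-square per degree of freedom between replicates, over the tested genes, was 27.9 in IgG RIP, 14.7 in input and 7.97 in CPEB4 RIP.

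Messages of ribosomal proteins took a larger share of the counts in CPEB4 RIP, at 5.28% ± 0.0149 (SD, n = 2), than in IgG RIP, at 2.75% ± 0.00833 (n = 2), or input, at 2.34% ± 0.118 (n = 2). The protein-coding messages of the mitochondrial genome held 4.20% ± 0.177 of the counts in CPEB4 RIP, 1.05% ± 0.187 in IgG RIP and 1.31% ± 0.176 in input (SD, n = 2 each). Each pair of groups was separated in both shares by more than the spread between replicates, except for mitochondrial messages in IgG RIP and input. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333, and no test of these shares was run. The heparan sulfate proteoglycan Sdc4 alone took between 4.31% and 5.91% of the counts in each library. The replicates of CPEB4 RIP and of input were close to each other, with Pearson r of log CPM (counts scaled to 1e+06 per library) across 18054 genes of 0.981 and 0.975. The IgG RIP libraries were farther apart at r = 0.873, the lowest value of any pair of libraries. IgG RIP replicate 1 lay closer to the input libraries, at 0.939 and 0.933, than to its own replicate. It was also closer to the CPEB4 RIP libraries, at 0.897 and 0.891. IgG RIP replicate 2 likewise lay closer to the input libraries (0.898 and 0.895) and the CPEB4 RIP libraries (0.899 and 0.902). At equal depth 30953 genes were expected with at least 1 count in IgG RIP replicate 1 and 21795 in replicate 2.

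**Figure D1:**
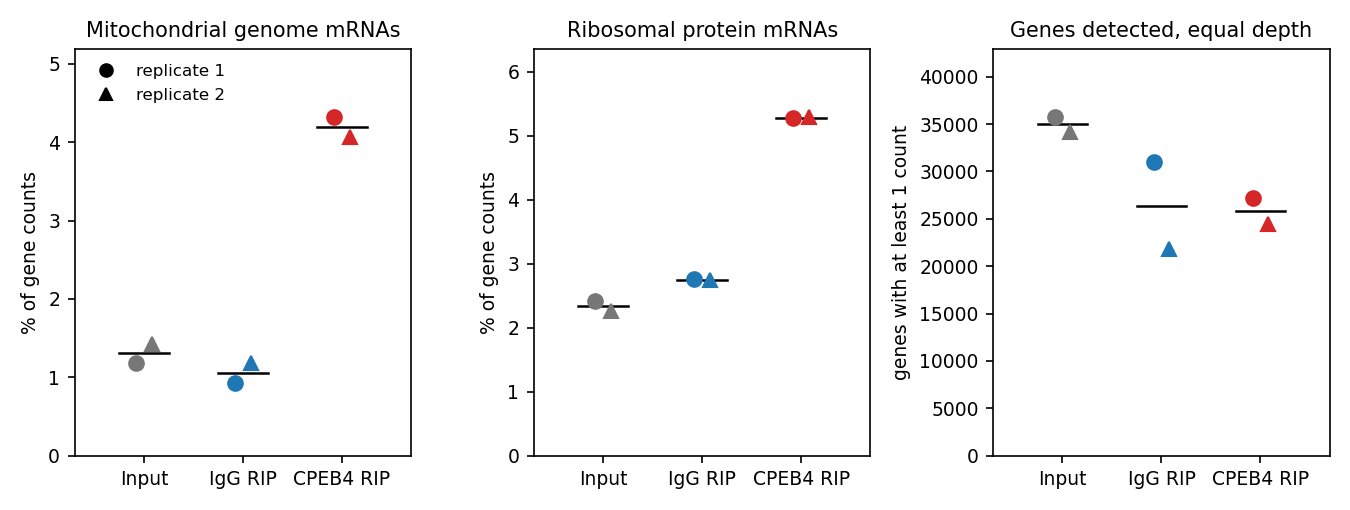
Share of gene counts in mRNAs of the mitochondrial genome (left, %), share in ribosomal protein mRNAs (middle, %) and genes expected with at least 1 count at the lowest depth (right, number of genes) for the 6 libraries. Circles are replicate 1, triangles replicate 2 and lines group means; CPEB4 RIP lies above both other groups in the first plots, with means of 4.20% and 5.28%, and the IgG RIP libraries lie apart in the last, at 30953 and 21795 genes.

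The comparison of CPEB4 RIP with IgG RIP, the one named in the design text, asks which RNAs the CPEB4 antibody recovered above a nonspecific antibody. Messages of ribosomal proteins and many messages of mitochondrial proteins were above IgG, and several chaperone messages were below it. Of 82 messages of cytosolic ribosomal proteins, 69 were higher, 0 were lower and 13 did not pass; adjusted over the list alone, 77 were higher. Rplp0, a protein of the ribosomal stalk, stood at 4075 ± 3.89 CPM in CPEB4 RIP against 994 ± 3.96 in IgG RIP and 1416 ± 11 in input (SD, n = 2 each). Its log2 fold change over IgG was 2.04 (SE 0.12, adjusted p = 0.00316) in edgeR's quasi-likelihood test. Rps2 (1.92), Rpl12 (2.10) and Rps12 (2.52) rose as well. Rplp0 lies on chromosome 5, 115559467 to 115563729 and Rpl12 on chromosome 2, 32961712 to 32964045 (GRCm38, mm10). The median of the list was 1.01, and camera with a preset correlation of 0.01 gave an adjusted p of 3.22e-23. With an estimated correlation between the genes the adjusted p was 0.584. Ribosomal protein genes have many processed pseudogenes of near-identical sequence, and how reads with several matches were counted is not given in the sources used here, so single members are uncertain.

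All 13 protein-coding messages of the mitochondrial genome had a fitted level above IgG, and 9 passed the test (11 adjusted over the list alone). They encode core subunits of the respiratory chain. The complex I subunit mt-Nd1 rose 5.63-fold, from 917 ± 157 CPM in IgG RIP to 5165 ± 322 in CPEB4 RIP (SD, n = 2 each), a log2 fold change of 2.49 (SE 0.16, adjusted p = 0.00316). The cytochrome c oxidase subunits mt-Co1 (2.56) and mt-Co3 (2.69), mt-Nd4 (2.30) and mt-Cytb (2.07) rose too. So did the ribosomal RNAs of the mitochondrion, mt-Rnr1 (2.46, MT 70 to 1024) and mt-Rnr2 (2.81, MT 1094 to 2675). The list median was 2.07, with a camera adjusted p of 7.62e-08 and an adjusted p of 0.584 with an estimated correlation.

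Nuclear genes for mitochondrial proteins included both directions. Of 78 nuclear subunits of the respiratory chain and ATP synthase, 34 were higher and 4 lower (52 and 5 adjusted over the list alone), with a median of 0.69. The complex I subunits Ndufa1 (1.42, SE 0.15) and Ndufb9 (1.45, SE 0.16) and the cytochrome c oxidase subunit Cox8a (1.30, SE 0.15) had the smallest p. The 4 lower members, picked out after their values were seen, were Ndufs1 (-1.16), Ndufv1 (-0.62), Uqcrc1 (-0.61) and Atp5a1 (-0.61). Among 77 genes listed for the mitochondrial ribosome 12 were higher, including Mrps24 (1.46) and Mrpl54 (1.18). Of the same list 1, Mrps27 (-1.20, chosen after its value was seen), was lower. Adjusted over the list alone the counts were 24 and 1. Of 23 import components 7 were higher and 0 lower (8 and 0 over the list alone), among them the inner membrane translocase subunits Timm23 (1.14) and Timm13 (0.96) and the outer membrane receptor Tomm20 (1.16). Of 21 enzymes of the tricarboxylic acid cycle 0 were higher, 3 were lower (4 over the list alone), including Ogdh (-0.72) and Mdh2 (-0.61), and 18 did not pass. Camera adjusted p was 2.18e-08 for the respiratory chain, 7.97e-04 for the mitochondrial ribosome, 0.0103 for import and 0.0450 for the cycle (median -0.30). Each of the 4 lists had an adjusted p of 0.584 with an estimated correlation. The import list lost its call without IgG RIP replicate 1, with an adjusted p of 0.120, and the cycle list lost its call in each of the 6 fits that left out 1 library (0.163 to 0.741).

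Several chaperone messages were below IgG. Of 15 cytosolic heat shock genes 0 were higher and 5 lower (7 over the list alone), with a median of -0.51 and a camera adjusted p of 0.0137; with an estimated correlation the adjusted p was 0.584. The chaperone Hspa8 fell from 8832 ± 989 CPM in IgG RIP to 3667 ± 60.4 in CPEB4 RIP (SD, n = 2 each), a log2 fold change of -1.27 (SE 0.12, adjusted p = 0.00719). Hsp90aa1 (-0.95) and Dnaja1 (-0.59) fell too. This list's call was lost without CPEB4 RIP replicate 1 (adjusted p 0.182), CPEB4 RIP replicate 2 (0.0545), input replicate 2 (0.0512), IgG RIP replicate 1 (0.175) or IgG RIP replicate 2 (0.234). Without CPEB4 RIP replicate 1 the median was -0.25 and without replicate 2 -0.50, with 0 members lower in both fits; it was -0.33 without IgG RIP replicate 1. Among 23 genes of endoplasmic reticulum chaperones and the unfolded protein response, 2 were higher and 6 lower (4 and 7 over the list alone), with no call for the list (adjusted p 0.826, median -0.03, mean 0.00 on the log2 scale). Hspa5, the main chaperone of this compartment, was the most strongly lowered at -1.53 (SE 0.13, adjusted p = 0.00542), on chromosome 2, 34772090 to 34776529. Its CPM was 4299 ± 605 in CPEB4 RIP, 12410.1 ± 374 in IgG RIP and 17320.1 ± 774 in input. Herpud1 (-1.11) was also lower, while the stress transcription factor Atf4 (1.05) was higher. The 21 mitochondrial chaperones, proteases and regulators held 3 higher and 4 lower members (4 and 4 over the list alone). Atf4 and its relative Atf5 (1.08, chosen after its value was seen) were higher, and the chaperones Trap1 (-1.33) and Hspd1 (-0.80) were lower; camera's adjusted p was 0.931.

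**Figure D2:**
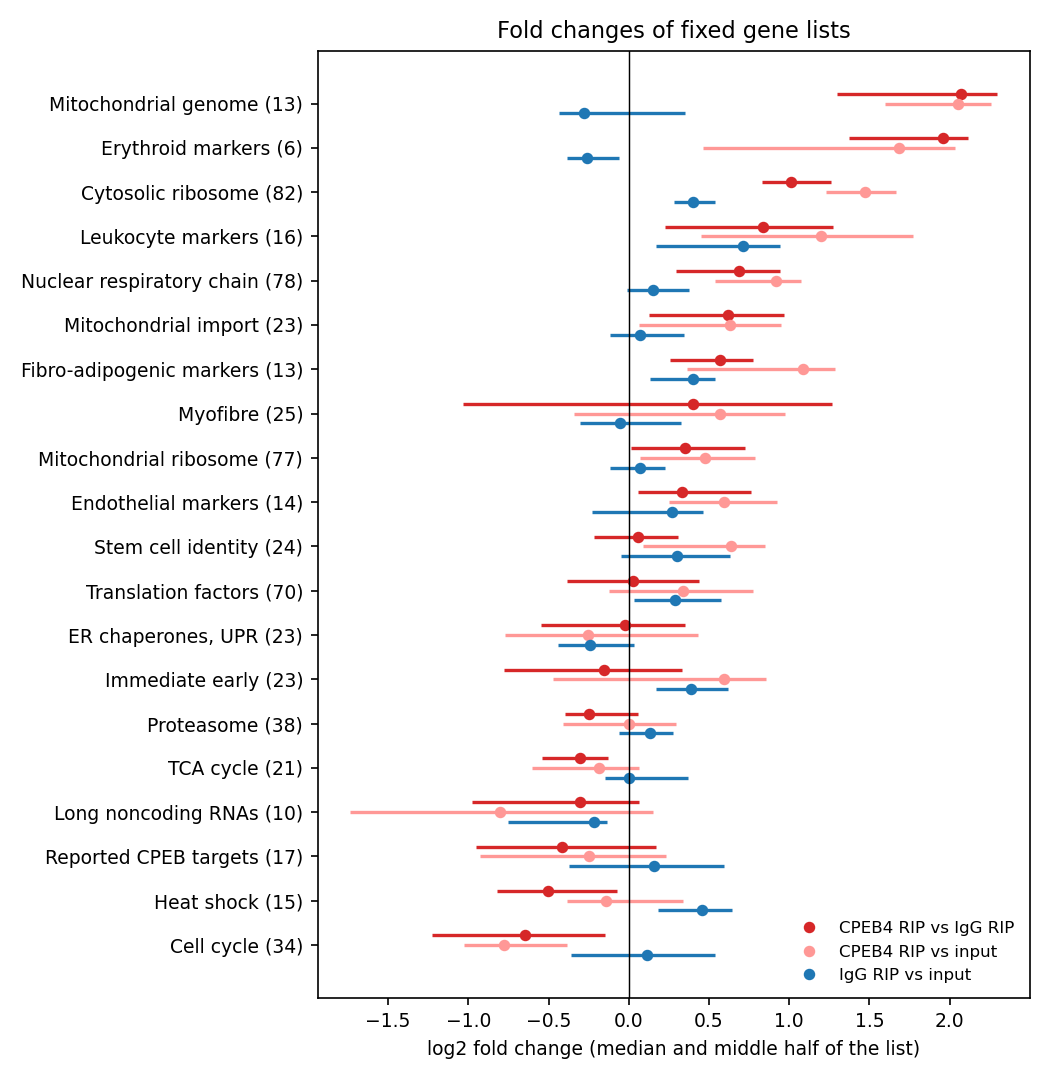
Log2 fold change of 20 of the fixed gene lists in the 3 comparisons, with the number of measured members in brackets. Points are list medians and bars run from the 25th to the 75th percentile of the members; the mitochondrial genome list lies at 2.07 over IgG RIP, 2.05 over input and -0.28 for IgG RIP over input.

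Growth and signalling messages included both directions. Of 23 immediate early genes 3 were higher and 6 lower (3 and 8 over the list alone, camera adjusted p 0.416). The phosphatase gene Dusp1 (-1.11) and Myc (-1.28, adjusted p = 0.00789) were lower and the transcription factor Klf4 (1.04) was higher. Messages reported as CPEB family targets in other cells had 0 of 17 members higher and 3 lower, namely Myc, the plasminogen activator gene Plat (-1.02) and Trp53 (-0.80). Adjusted over the list alone, 2 were higher and 5 lower, and camera's adjusted p was 0.206. The list median was -0.41 over IgG and -0.25 over input, where 1 was higher and 3 lower (the same over the list alone) and camera's adjusted p was 0.244. The fry test, which asks whether a list's genes move one way without comparing them with other genes, gave an adjusted p of 0.0390 over IgG and 0.0317 over input. Cpeb4 itself (chromosome 11, 31870104 to 31935635) stood at 15.7 ± 1.11 CPM in CPEB4 RIP, 20.8 ± 13.9 in IgG RIP and 13.4 ± 0.30 in input (SD, n = 2 each), with a log2 fold over IgG of -0.41 (SE 0.44, adjusted p = 0.578). The stem cell genes did not pass: Pax7 stood at 0.24 with an adjusted p of 0.499, Myf5 at -0.02 with 0.978 and Myod1 at 0.00 with 0.990. Without IgG RIP replicate 2, Myf5 turned to 0.80 (adjusted p = 0.00771), Pax7 stood at 0.69 (0.00666) and Cpeb4 at 0.65. Without IgG RIP replicate 1, Cpeb4 stood at -0.79 (0.0119). Of 24 genes of stem cell identity 1, the receptor Fgfr4 (0.75), was higher and 1, the adhesion gene Vcam1 (-0.87), was lower; both were picked out after their values were seen. The list's median was 0.06 and its adjusted p 0.894, with 2 higher and 1 lower over the list alone.

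Cell cycle genes had low fitted levels in CPEB4 RIP, with a median of -0.65 over 34 genes and a camera adjusted p of 0.0310. The list's adjusted p was 0.584 with an estimated correlation. Only Rrm1 (-1.19), a subunit of ribonucleotide reductase, and Top2a (-1.77) passed over all genes, and 0 did over the list alone. The call was lost without CPEB4 RIP replicate 1 (0.0776) or 2 (0.0835), without IgG RIP replicate 1 (0.120) or 2 (0.234), and without input replicate 2 (0.0523). A low median was not particular to the cell cycle list. Olfactory receptor genes (Olfr) had a median of -2.39 over 138 genes, with 0 higher and 4 lower. Vomeronasal receptor genes (Vmn) had a median of -2.48 over 63 genes, with 0 higher and 3 lower. Long noncoding RNAs, several of them held in the nucleus, had 0 of 10 members higher and 3 lower: Kcnq1ot1 (-1.94), Rian (-1.12) and Meg3 (-1.09), with 1 higher and 3 lower over the list alone and no camera call for the list (adjusted p 0.199, against 0.0206 with fry). Of 38 proteasome subunits 1, Psmd10 (1.62), was higher and 5 were lower, including Psmd2 (-1.07) and Psmc4 (-0.67); over the list alone the counts were 2 and 6, with adjusted p 0.130. Translation factors had 7 of 70 higher and 3 lower (9 and 6 over the list alone, adjusted p 0.931), with Eif3f at 1.15, Eef1b2 at 0.76 and Eif3c at -0.83. Among 20 genes of mitochondrial biogenesis and dynamics 2 were higher and 0 lower, over all genes as over the list alone (adjusted p 0.477). They were Pink1 (1.57), a kinase of mitochondrial quality control, and the fission gene Fis1 (0.86), both singled out after their values were seen. The 30 genes of poly(A) addition and deadenylation held 0 higher and 2 lower members, the deadenylase Parn (-1.32) and Fip1l1 (-0.86), singled out in the same way (2 and 3 over the list alone, adjusted p 0.416). The 11 replication histones had a median of -0.04 and an adjusted p of 0.894, with 0 members past the test over all genes or over the list alone.

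Markers of other cell types moved with CPEB4 RIP in part. The erythroid list, of 6 measured genes, had 3 higher (4 over the list alone) and 0 lower, at a median of 1.96 with a camera adjusted p of 0.0450; with an estimated correlation the adjusted p was 0.584. The hemoglobin genes Hba-a1 (2.06), Hba-a2 (1.86) and Hbb-bs (2.13) were the members that rose, and as near-identical copies they are uncertain as single genes. Hba-a1 stood at 333 ± 169 CPM in CPEB4 RIP and 79.6 ± 20.7 in IgG RIP. The erythroid call was lost without CPEB4 RIP replicate 1 (0.0615), input replicate 2 (0.0512), IgG RIP replicate 1 (0.115) or IgG RIP replicate 2 (0.126). Higher erythroid members numbered 0 without either CPEB4 RIP replicate, at medians of 1.65 and 2.38, and 1 without either input replicate. Of 16 leukocyte markers 1, the neutrophil calcium-binding protein S100a8 (2.54), was higher (2 over the list alone, list adjusted p 0.145). Fibro-adipogenic markers had 2 of 13 higher, Col3a1 (0.57) and Mfap5 (1.40) (3 higher and 1 lower over the list alone, adjusted p 0.121). Endothelial markers had 1 of 14 higher, Fabp4 (1.11) (2 over the list alone, adjusted p 0.162). Pericyte and smooth muscle markers had 0 of 10 past the test, also over the list alone (adjusted p 0.993, median -0.03 with a mean of 0.09). Tenocyte and Schwann cell markers had 1 of 9 lower, Ncam1 (-0.73), over all genes and over the list alone (adjusted p 0.894). Matrix genes of the niche had 1 of 20 lower, Lama2 (-0.77) (1 higher and 2 lower over the list alone, adjusted p 0.894). Among 25 myofibre genes 4 were higher (6 over the list alone, adjusted p 0.297), including the troponins Tnnt3 (1.39) and Tnni2 (1.5) and the myosin light chain Myl1 (1.68). The single members named here for markers of other cell types, apart from the hemoglobins, S100a8 and the myofibre genes, were chosen after their values were seen.

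In all, 1482 of 18054 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 864 of them higher and 618 lower in CPEB4 RIP, and 1012 changed at least 2-fold. At an unadjusted p under 0.05 there were 4838 genes, where chance gives 903. Among genes above 10 CPM the widest rise was that of Telo2, a cochaperone of PI3K-related kinases, at 3.80 (SE 0.54, adjusted p = 0.0120); its CPM was 18.9 ± 3.39 against 1.39 ± 0.899 in IgG RIP and 10.4 ± 4.08 in input. Nucleoredoxin, Nxn, followed at 2.94 (SE 0.27, adjusted p = 0.00650), then mt-Rnr2, Cdk2ap1 (2.73), mt-Co3, Taf10 (2.57), mt-Co1, S100a8, Rps12 and mt-Nd1. Over input Telo2 stood at 0.86, which did not pass (adjusted p = 0.271). The widest falls were those of Gdap10 (-2.67, SE 0.36, adjusted p = 0.0106), Nup133 (-2.24), a nuclear pore protein, Mfsd4a (-2.13), Ankrd26 (-2.04) and Fxyd4 (-1.94). Telo2 lies on chromosome 17, 25099569 to 25115974 and Gdap10 on chromosome 12, 32824116 to 32826919. Filter and scaling were redone in each fit that left out a library, and list medians could move together. Without input replicate 1, which is not in this comparison, the ribosomal protein median went from 1.01 to 1.15 and heat shock from -0.51 to -0.37. Without CPEB4 RIP replicate 1 the heat shock median went up to -0.25, as did those of the rising lists given below. The erythroid median went down from 1.96 to 1.65. Scaling by library size alone changed the split from 58.3% to 46.8% higher. Without CPEB4 RIP replicate 2 the count was 0 and without replicate 1 it was 204; without input replicates 1 and 2 it was 970 and 972; without IgG RIP replicates 1 and 2 it was 7710 and 7405, fits in which the lone IgG RIP library is assumed to vary like the other groups. In the same fits the number of higher ribosomal protein messages was 0 without CPEB4 RIP replicate 2 and 45 without replicate 1, at list medians of 1.01 and 1.30. The higher respiratory chain messages numbered 0 and 12 (medians 0.70 and 0.96) and those of the mitochondrial genome 0 and 7 (2.07 and 2.33).

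**Figure D3:**
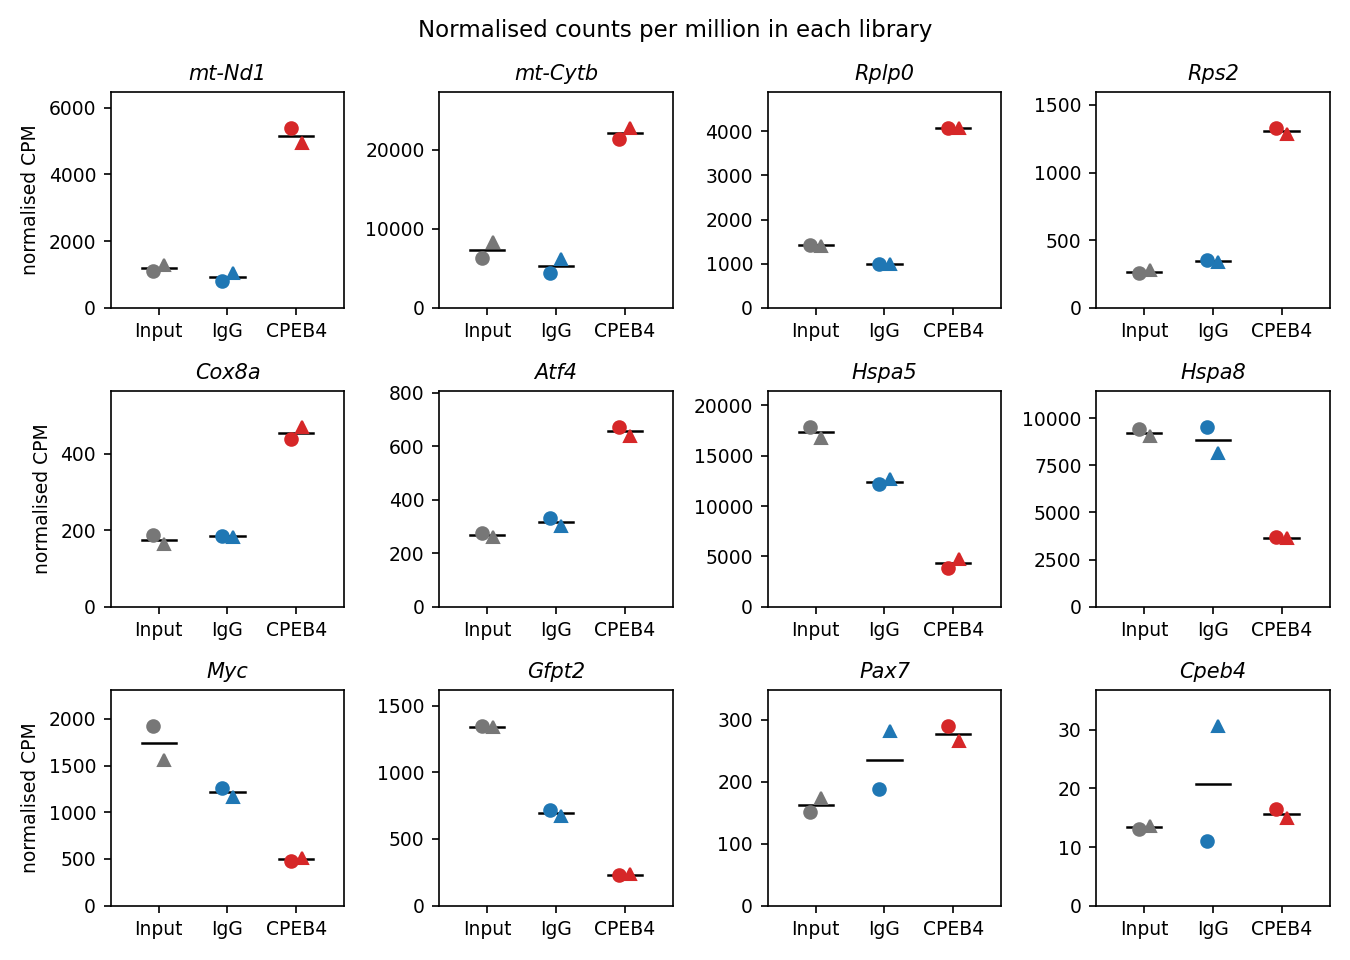
Normalised CPM of 12 genes in each library, with circles for replicate 1, triangles for replicate 2 and lines for group means; each panel has its own axis from 0. Rplp0 (mean 4075) and mt-Nd1 (5165) lie above both other groups in CPEB4 RIP, Hspa5 (4299) and Gfpt2 (233) lie below both, and the IgG RIP libraries are far apart for Cpeb4.

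The fold changes followed gene length. Gene length here is relative, from the ratio of counts to FPKM. Across 18054 genes, which are not independent replicates, Spearman's rho of log2 fold over IgG with length was -0.20, and it was -0.25 for CPEB4 RIP over input and -0.09 for IgG RIP over input. The shortest 10% of genes had a median of 0.53 over IgG and the longest 10% -0.40. With the length trend removed by an offset, an alternative chosen after seeing the data, 520 genes passed over IgG. The ribosomal protein list then had a median of 0.79 with 29 of 82 higher, the nuclear respiratory chain list 0.44 with 5 of 78 higher, and the mitochondrial genome list 1.82 with 8 of 13 higher. The calls over IgG of the tricarboxylic acid cycle (median -0.38, adjusted p 0.0550), cell cycle (-0.69, 0.0550) and erythroid (1.66, 0.0574) lists were lost, at medians of -0.30, -0.65 and 1.96 before. Over input the leukocyte (1.10, 0.0560) and noncoding RNA (-0.38, 0.270) calls were lost, at medians of 1.2 and -0.80 before. Over input 1491 genes passed with the offset, and the ribosomal protein, nuclear respiratory chain and mitochondrial genome lists had medians of 1.33 with 69 of 82 higher, 0.67 with 21 of 78 higher and 1.68 with 8 of 13 higher.

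**Figure D4:**
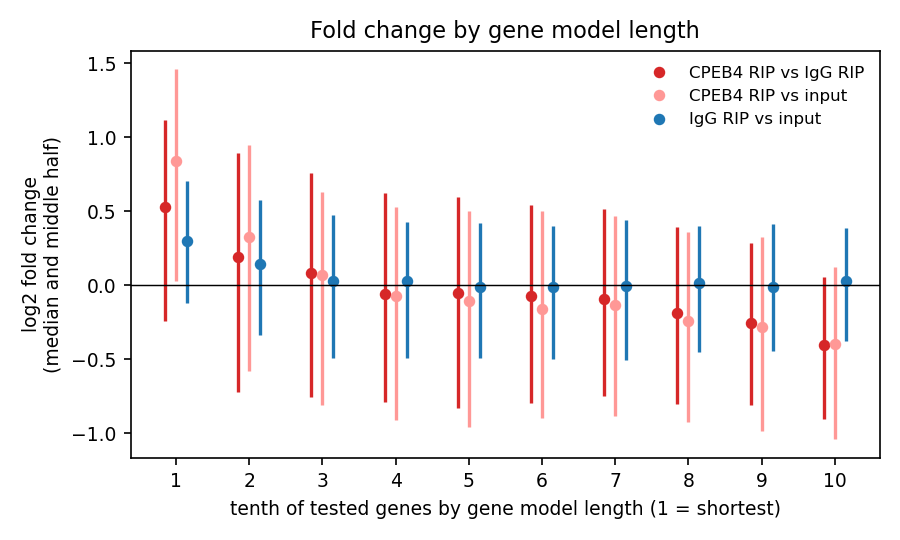
Median log2 fold change (points) of the tested genes in 10 bins of equal size by gene length, bin 1 being the shortest, for the 3 comparisons, with bars from the 25th to the 75th percentile. For CPEB4 RIP over IgG RIP the median falls from 0.53 in the shortest bin to -0.40 in the longest, and for IgG RIP over input it is 0.30 in the shortest and 0.03 in the longest.

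The comparison of CPEB4 RIP with input asks which RNAs were enriched over their abundance in the cells. Ribosomal and mitochondrial messages stood above input too: 76 of 82 ribosomal protein messages (77 adjusted over the list alone) and 53 of 78 nuclear respiratory chain messages (63 over the list alone) were higher, with medians of 1.47 and 0.92. Of the respiratory chain messages 3 were lower, also over the list alone. Rps2 rose from 267 ± 15.3 CPM in input to 1306 ± 33.5 (SD, n = 2 each), a log2 fold of 2.29 (SE 0.13, adjusted p = 0.00184). The mitochondrial genome list had 9 of 13 higher (10 over the list alone) at a median of 2.05, with mt-Nd4 at 2.42 and mt-Nd1 at 2.12. Mitochondrial import (9 of 23 higher, Timm13 0.91) and mitochondrial ribosome (16 of 77 higher and 1 lower, Mrpl54 1.15) lists rose too, with 11 higher, and 28 higher and 1 lower, over each list alone. Translation factors rose as a list, with 19 of 70 higher and 3 lower (23 and 6 over the list alone), such as Eif3f (1.68) and Eef1b2 (1.17). Camera's adjusted p was 7.50e-34 for ribosomal proteins, 2.03e-13 for the nuclear respiratory chain, 3.84e-08 for the mitochondrial genome, 2.94e-05 for the mitochondrial ribosome, 0.00247 for import and 0.00937 for translation factors. The adjusted p of these 6 lists with an estimated correlation lay between 0.499 and 0.618. The chaperones Hspa5 (-2.01) and Hspa8 (-1.33) were below input too. Hsp90aa1 (-0.20, adjusted p = 0.295) and Dnaja1 (-0.14, adjusted p = 0.528) did not pass over input, and Hsp90aa1 stood at 0.75 in IgG RIP over input (adjusted p = 0.153). The endoplasmic reticulum list (2 of 23 higher and 7 lower, adjusted p 0.244) and the heat shock list (1 of 15 higher and 2 lower, adjusted p 0.818) were not called. The tricarboxylic acid cycle list (median -0.18, adjusted p 0.244) and the erythroid list (median 1.68, adjusted p 0.104) were not called over input either. The cycle list had 2 of 21 members higher than input and 3 lower (3 and 7 over the list alone). Nor were the pericyte and smooth muscle list (1 of 10 higher, 3 over the list alone, median 0.56, adjusted p 0.129) and the tenocyte and Schwann cell list (1 of 9 higher, also over the list alone, median 0.54, adjusted p 0.261). Immediate early genes had 9 of 23 higher than input and 5 lower (12 and 7 over the list alone, camera adjusted p 0.244). Their median was 0.59 over input, against -0.15 over IgG.

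Of 24 stem cell identity genes 6 were higher than in input and 2 lower (11 and 2 over the list alone), with a median of 0.64 and a camera adjusted p of 0.0158; with an estimated correlation the adjusted p was 0.499. Desmin, Des (0.99), and Notch3 (1.02) were among the higher members, and the lower ones were Vcam1 (-1.18) and the calcitonin receptor gene Calcr (-1.38), all singled out after their values were seen. Pax7 stood at 0.77 (SE 0.21, adjusted p = 0.0531), Myf5 at 0.98 (SE 0.43, adjusted p = 0.182), Myod1 at 0.28 (SE 0.14, adjusted p = 0.227) and Cpeb4 at 0.23 (SE 0.44, adjusted p = 0.771). Without IgG RIP replicate 1 or 2, Pax7 (0.83 in both fits) and Myf5 (1.05 and 1.06) passed. Some markers of other cells were higher than in input. Fibro-adipogenic genes had 5 of 13 higher (7 over the list alone), with Col3a1 at 1.17, leukocyte genes 2 of 16 (2 over the list alone), with S100a8 at 1.85, niche matrix genes 5 of 20 with 1 lower (the same over the list alone), and endothelial genes 2 of 14 with 1 lower (3 and 1 over the list alone). Camera's adjusted p was 0.00906, 0.0158, 0.00906 and 0.0477 in that order. With an estimated correlation the adjusted p was 0.513 for the first 3 and 0.679 for endothelial genes. The leukocyte call was lost without input replicate 1 (0.0764), and the endothelial call without CPEB4 RIP replicate 1 (0.123) or input replicate 1 (0.0870). The cell cycle (median -0.78, 2 of 34 lower, 1 over the list alone, adjusted p 0.0154) and long noncoding RNA (median -0.80, 3 of 10 lower, 1 higher and 3 lower over the list alone, adjusted p 0.0477) lists fell. With an estimated correlation their adjusted p was 0.499 and 0.513. Here too other genes had low medians, at -2.47 for Olfr and -2.34 for Vmn genes. The cell cycle call was lost without CPEB4 RIP replicate 1 (0.0685) or 2 (0.0592) or input replicate 2 (0.0935). The noncoding RNA call was lost in 5 of the 6 fits that left out 1 library; it held without CPEB4 RIP replicate 2.

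The widest rise over input among genes above 10 CPM was that of the transcription factor gene Cebpb, at 3.93 (SE 0.54, adjusted p = 0.00530), from 5.33 ± 1.08 CPM to 80.8 ± 12.1. It stood at 21.5 ± 16.3 CPM in IgG RIP and did not pass over IgG (1.90, adjusted p = 0.0548). Lars2 (3.25), Igfbp7 (2.77), Abhd17a (2.60), Rps12 (2.59) and Pnrc1 (2.45) followed, with mt-Te (3.04), mt-Nd6 (2.63), mt-Rnr1 (2.42) and mt-Nd4 from the mitochondrial genome. The mouse Lars2 gene model is known to hold a stretch resembling ribosomal RNA, so its reads may come from elsewhere. mt-Nd6 and mt-Te lie on the strand opposite most mitochondrial genes, and the counting is not stated to use strand, so both are uncertain. The widest falls were in Mir17hg (-4.01, SE 0.25, adjusted p = 0.00184), the host transcript of a microRNA cluster, then Gdap10 (-3.35), Mfsd4a (-2.83), the deubiquitinase gene Usp33 (-2.72) and Gfpt2 (-2.53), an enzyme of the hexosamine pathway. Gfpt2 stood at 233 ± 4.75 CPM in CPEB4 RIP, 695 ± 35.7 in IgG RIP and 1343 ± 7.12 in input, on chromosome 11, 49794155 to 49838620. In total 2294 genes passed, 1445 higher and 849 lower, with 1623 changed at least 2-fold and 5070 at an unadjusted p under 0.05. With library size alone the split went from 63.0% to 43.7% higher, and the median gene shifted by -0.21. Without CPEB4 RIP replicates 1 and 2 the counts were 650 and 117, without input replicates 1 and 2 they were 623 and 756, and without IgG RIP replicates 1 and 2 they were 7966 and 7942. In the fit without CPEB4 RIP replicate 2 the higher messages numbered 34 for ribosomal proteins, 0 for the nuclear respiratory chain and 6 for the mitochondrial genome. The respiratory chain count was 34 without CPEB4 RIP replicate 1 and 16 and 30 without input replicates 1 and 2.

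There were 645 genes higher than both IgG RIP and input, and 422 lower than both, with 0 in opposite directions. Of the genes higher than IgG, 74.7% were also higher than input. Among named genes above 10 CPM, the 5 with the widest smaller fold were Rps12, mt-Rnr1, mt-Rnr2, mt-Nd4 and mt-Co1. Rps12 stood at 319 ± 28.1 CPM in CPEB4 RIP, 55.6 ± 9.79 in IgG RIP and 53.1 ± 4.30 in input. Independent lists of these sizes would share 69.2 higher and 29.1 lower genes. In 20 simulations of unchanged groups that share the CPEB4 libraries at most 1 gene passed in either comparison, so the simulations give no scale for a shared count. The fold changes correlated at r = 0.70 across genes, against 0.49 in the simulations, and their covariance was 1.38 against 0.375, a difference of 1.01. The simulated values already include the sharing of libraries at the simulated spread. With 2 CPEB4 RIP libraries a split would leave 1 on each side, so an effect of sharing beyond that spread was not tested. The count was 0 without CPEB4 RIP replicate 2, 162 without replicate 1, 283 and 395 without input replicates 1 and 2, 2286 and 2717 without IgG RIP replicates 1 and 2, and 246 with the length trend removed.

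The comparison of IgG RIP with input shows what an immunoprecipitation without a specific antibody does to the RNA. In edgeR's quasi-likelihood test 0 genes passed, with 2550 at an unadjusted p under 0.05, where chance gives 903; the smallest adjusted p was 0.0867 and DESeq2 called 706. Chrdl2 (1.31), Lars2 (1.84), Irs2 (1.56) and Nr4a3 (1.36) were among the genes above 10 CPM with the smallest p on the higher side. On the lower side Mir17hg (-2.15), Slc20a1 (-1.54), Gfpt2 (-0.95) and Mars (-1.53) were among them; none of these 8 passed. Cpeb4 (0.65), Pax7 (0.53), Myf5 (1.01) and Myod1 (0.29) did not pass either. Without IgG RIP replicate 1, Cpeb4 (1.07), Pax7 (0.67) and Myf5 (1.35) did. Without IgG RIP replicate 2, Cpeb4 stood at -0.36 and did not pass (adjusted p = 0.482). As a list, ribosomal protein messages were slightly higher, with a median of 0.40 and a camera adjusted p of 1.48e-10, 0 of 82 members past the test over all genes, and 30 higher and 1 lower over the list alone. DESeq2 called 28 of them higher and 1 lower, as did the fit without IgG RIP replicate 1; without IgG RIP replicate 2 the median was 0.23 with 5 higher. The translation factor (0.29), heat shock (0.46), immediate early (0.39), niche matrix (0.46), pericyte and smooth muscle (0.43), stem cell identity (0.30) and nuclear respiratory chain (0.15) lists also had camera adjusted p between 5.44e-04 and 0.0362. With an estimated correlation the adjusted p was 0.748 for all of these except the respiratory chain, at 0.823, and none of the 8 calls held. Without IgG RIP replicate 2 only the ribosomal protein call of the 8 was left, there were 4 list calls without IgG RIP replicate 1, and 5 without input replicate 1, where the respiratory chain median turned to -0.055. With library size alone, which shifts the median gene by -0.13, that median was 0.0082. The mitochondrial genome list stood at a median of -0.28 with a mean of 0.00, and its adjusted p was 0.974. Its median was -0.63 without IgG RIP replicate 2, with 2 members higher and 6 lower, without IgG RIP replicate 1 it was -0.13 with 3 higher and 1 lower, and without input replicate 1 it was -0.18 with none past the test. Without IgG RIP replicates 1 and 2 the gene counts were 6657 and 1739.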

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

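The gene length offset and thinning to equal depth were chosen after seeing the data; the other alternatives were planned. Over IgG the count of 1482 became 2428 with no low-count filter, 2892 in DESeq2, 973 with only the 4 libraries compared, 318 in limma on FPKM with no filter and 520 with the length offset (509 shared). With a library left out it ranged from 0 to 7710. Over input the count of 2294 became 3479 in DESeq2, 7340 with only the 4 libraries compared, 908 in limma on FPKM with no filter and 1491 with the length offset (1354 shared), and ranged from 117 to 7966 with a library left out. For IgG RIP over input the count of 0 became 457 with no filter, 706 in DESeq2, 25 with a replicate term, 1 in each limma fit on FPKM and 2 after thinning, and ranged from 0 to 6657. Genes above both backgrounds numbered 1077 with no filter, 1107 in DESeq2, 402 at 2-fold or more and 246 with the length offset (235 shared), and 0 to 2717 with a library left out.

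With an estimated correlation 0 lists were called in all 3 comparisons. List calls for IgG RIP over input were 0 with fry and 5 with library size alone. With fry the calls were 10 over IgG and 9 over input. It lost heat shock (0.0687) over IgG, and translation factors (0.0706), fibro-adipogenic (0.0706), leukocyte (0.0706), endothelial (0.333) and niche matrix genes (0.0664) over input. It gained reported CPEB targets in both (0.0390, 0.0317) and noncoding RNAs over IgG (0.0206). With a library left out the calls numbered 4 to 9 over IgG, 10 to 16 over input and 1 to 8 for IgG RIP over input. Removing a library leaves fewer residual degrees of freedom, and a lone library is assumed to vary like the other groups. With only the 4 libraries compared, IgG RIP libraries no longer enter the spread over input, nor input libraries that over IgG. How far this moved the counts, and the cause for the other settings, was not tested.

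Pax7 over input (0.77) passed with DESeq2 size factors (0.71), without mitochondrial genes (0.77), with no filter (0.88), a mean count of 20 (0.62), DESeq2 (0.72), only 4 libraries (0.73) and a replicate term (0.78). Myf5 over input (0.98) passed with no filter (1.10), only 4 libraries (0.95) and a replicate term (1.04), and Myf5 in IgG RIP over input with no filter (1.06). With a library left out, values over IgG ranged from -0.79 to 0.65 for Cpeb4, 0.16 to 0.69 for Pax7, -0.30 to 0.80 for Myf5 and -0.02 to 0.27 for Myod1. Those over input ranged from 0.23 to 0.37, 0.69 to 0.90, 0.60 to 1.57 and 0.21 to 0.46 in the same order. Those of IgG RIP over input ranged from -0.36 to 1.07, 0.14 to 0.67, 0.26 to 1.43 and 0.07 to 0.30. Myf5 over IgG turned to 0.80 without IgG RIP replicate 2, and the respiratory chain list in IgG RIP over input turned to -0.055 without input replicate 1 (range -0.055 to 0.17 with a library left out). Cpeb4, which passed in neither fit, changed sign without IgG RIP replicate 2 over IgG (0.65) and in IgG RIP over input (-0.36). The cause was not tested.

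Results were counted by setting, apart from the gene and list counts and the 4 genes above. Of these, 4149 for single genes and 833 for single lists kept their side of the threshold, with the same direction where called. Of the rest, 849 and 115 lost their call and 224 and 23 gained one. The list results include those lost with an estimated correlation and the 1 called list that turned, both given above. Direction was not compared where neither fit made a call, so results that changed sign may be among those that kept their side. A replicate term gave 1850 genes over IgG and 2615 over input. The replicate numbers pair the groups by label alone: same-number deviations correlated across genes at -0.016 for CPEB4 RIP with input, 0.13 for CPEB4 RIP with IgG RIP and 0.07 for input with IgG RIP. The planned test for the cytoplasmic polyadenylation element and its alternatives were not run. In simulated data with 200 genes changed 2-fold or 4-fold and a list shifted by less, 2-fold changes were mostly missed (9% recovered). The edgeR test made 65 calls there, against 1482 over IgG in the measured libraries. The Benjamini-Hochberg cut-off is stricter where fewer genes pass, so recovery in the measured comparison over IgG is not given by this simulation.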

Other observations

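The families of genes with a shared symbol stem and the tests of carried mitochondria, carried ribosomes and a lower share of stem cell RNA were chosen after the results were seen. For the length tests and the count of undetected genes the bounds were set before their values were seen, but the length offset and the thinning they use were chosen after seeing the data. Among 86 symbol families of at least 15 members, tested in 172 tests per comparison against 13184 genes, protein phosphatase genes (Ppp) had 13 of 62 members higher and 3 lower over IgG (hypergeometric adjusted p = 9.78e-04). Over input 14 were higher and 3 lower (adjusted p = 0.0208). Among the higher members over IgG were Ppp1cc (1.87), Ppp1ca (0.68), Ppp2ca (1.39), Ppp2cb (2.03), Ppp3cb (1.42) and Ppp3cc (2.84). Over input Ppp1ca (0.23, adjusted p = 0.361) and Ppp3cc (1.44, adjusted p = 0.0657) did not pass. These are catalytic subunits of phosphatases 1, 2A and calcineurin, of which Ppp1cb (0.12, adjusted p = 0.688) and Ppp3ca (0.62, adjusted p = 0.153) did not pass over IgG. Ppp1ccb (2.54) is a near-identical copy of Ppp1cc and uncertain as a single gene. The other higher members were not catalytic subunits: Ppp1r14b (2.19), Ppp2r5a (1.64), Ppp2r2d (1.46), Ppp1r2 (1.21), Ppp1r12c (0.91) and Ppp1r14a (0.81). The catalytic subunits of other phosphatases, Ppp4c (0.38), Ppp5c (-0.51) and Ppp6c (-0.31), did not pass over IgG. The lower members over IgG were Ppp1r15a (-0.83), Ppp2r1b (-0.82) and Ppp6r3 (-0.65). The family median was 0.28, and 0.32 with the length trend removed. The hypergeometric test, here and for the families below, treats genes as independent draws. It made no allowance for correlation between genes and was not repeated with a library left out.

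The DEAD-box RNA helicases (Ddx) went the other way over IgG, with 9 of 34 lower and 0 higher (adjusted p = 2.04e-04) and a median of -0.65. Ddx5 (-1.12), Ddx42 (-1.10), Ddx20 (-1.09), Ddx27 (-1.07) and Ddx1 (-0.97) were among the lower members. With the length trend removed the median was -0.61 and 3 were lower. Over input 6 Ddx genes were lower and 2 higher (adjusted p = 0.138). Ubiquitin-specific proteases (Usp) had 10 of 49 lower over input (adjusted p = 0.00941) and 4 lower with the length trend removed. The Usp median over input was -0.14, and it turned to 0.091 with the length trend removed. Over IgG 6 were lower and 1 higher (adjusted p = 0.211), with 1 lower after the length trend was removed. The 10 lower over input included Usp33 (-2.72), Usp15 (-1.80), Usp37 (-1.73), Usp8 (-1.22) and Usp9x (-1.15).

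The ribosomal protein, mitochondrial genome and nuclear respiratory chain lists lay above IgG RIP in CPEB4 RIP (69 of 82, 9 of 13 and 34 of 78 members higher), and the shortest 10% of genes had a median of 0.53. Removing the length trend left the ribosomal protein median at 0.79 (95% bootstrap interval 0.73 to 0.88, before 1.01) with 29 members past the test. It left the mitochondrial genome median at 1.82 (0.68 to 2.06, before 2.07) with 8. Both medians argue against length as the whole cause in these libraries. The intervals resample list members, which may move together, so they hold no spread between libraries. The nuclear respiratory chain went from 0.69 to 0.44 (0.36 to 0.59) with 5 members left. A positive median remained, but its interval met neither bound set beforehand, so how much of that rise length explains is undecided. Whole mitochondria carried along remain a candidate explanation for the mitochondrial genome messages, since the rRNAs mt-Rnr1 (2.46) and mt-Rnr2 (2.81) rose as well; carried ribosomes stay open, as the 3 measured features with cytosolic rRNA sequence had a median of -0.28, from -2.01 to 1.41. Binding by CPEB4 may contribute and was not tested by a measure of its own.

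Markers of other cell types were higher in part, though sorting should remove such cells. Hba-a1 stood at 333 ± 169 CPM in CPEB4 RIP and 105 ± 36.8 in input. Length does not settle the erythroid rise, as the list's median was 1.66 with the trend removed (-0.85 to 1.92, before 1.96), with 0 members past the test. The test took a lower share of stem cell RNA to raise markers of every other type alike. That need not hold if other cell types contribute unequally, a case this test cannot judge. This test replaced a first one on the stem cell identity list (median 0.06), whose high baseline would hide a small share. The lowest list median was -0.028 for pericytes and smooth muscle (-0.45 to 0.74) and the highest 1.96 for erythroid genes (-0.86 to 2.19), with leukocytes at 0.84 (0.23 to 1.21), fibro-adipogenic cells at 0.57 (0.26 to 0.78), endothelium at 0.33 (0.05 to 0.78) and tenocytes and Schwann cells at 0.00 (-0.73 to 0.70), intervals too wide to decide, so this explanation may hold or not.

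IgG RIP replicate 2 stood apart from replicate 1. Among genes at 1 to 5 CPM on average in the other 5 libraries, 900 had 0 counts in it after thinning to equal depth, against 216 in the highest other library, CPEB4 RIP replicate 2, by the same count. IgG RIP replicate 1 had 111. This is what fewer distinct RNA molecules in IgG RIP replicate 2 would give, but it is close to the same measure as the number of genes at equal depth (21795 against 30953) and adds little to it. No biological explanation was tested for this difference.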
